A study of Mus musculus with 4 samples.

How the data were processed

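ATAC-seq libraries were made from LT-HSCs of middle-aged C57BL/6 mice, 2 with vehicle (0.1% BSA in PBS) and 2 with IGF1 at 100 ng/ml for 18 h in 96-well plates. Per the labels, the libraries came from 2 independent replicates of pooled mice, so n = 2 per group. Nuclei were transposed and the DNA was amplified by PCR, per the labels' protocols. The series' text says that libraries of young mice are left out, and none was analysed here.

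The deposited table holds 1 score per peak and library over a shared set of peaks. Per the submitters' processing notes, R 3.6.0, DiffBind 2.12.0, edgeR 3.26.4 and HOMER 4.10 were used by the authors, with the builds mm10 and GRCm38; the role of each tool is not stated there. The aligner, the peak caller, the shift of reads for the transposase's cut and the treatment of duplicates are not given in the sources used here. Whether reads in repeats were kept is likewise not given. This bears on the ribosomal DNA peak and on the peaks on chromosome 2 and in Sfi1 named below, which may hold satellite repeats. The deposited scores are whole numbers but not raw counts. IGF1 1 leaves 72 low whole numbers unused and control 1 leaves 9, and in control 2 some values are held by more peaks than their neighbours, which is the pattern of counts multiplied by a factor and rounded. The value of 1 read was estimated per library as the factor under which the numbers of peaks at low values were most probable. It was 1.0582, 0.912, 1.8312 and 1 for control 1, control 2, IGF1 1 and IGF1 2, and dividing the sums by it gave about 46600000, 51800000, 27300000 and 48300000 reads in peaks. No value is 0. In control 2 several read counts share 1 value, so whole reads could not be recovered for each library.

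Because the values are not counts, the planned quasi-likelihood test for counts was replaced by the fallback written before the data were examined: limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend, on log2(value + 2). Differences are on that scale, which understates the change of weak peaks. Values were used as deposited, since the scaling had been done by the authors. Peaks with a mean value of at least 10 were tested (197481 of 205376), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The main model had treatment alone. The replicate number is read as marking a shared pool of mice, from the treatment protocol, which speaks of 2 replicates of pooled mice given vehicle or IGF1. The deviations of same-numbered libraries from their group means correlated at r = 0.054 over all tested peaks and at 0.250 over peaks with a mean value of at least 1000. The model with the number as a block was therefore also fitted. Libraries were compared for identical content, and at most 1.84% of peaks had equal values in any pair of libraries.

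Peaks were placed against protein-coding genes of the RefSeq annotation of GRCm38, the build of the coordinates. The annotation used here gave no strand, so gene starts could not be told from gene ends. A gene-end peak overlaps the window from 1000 bp outside to 100 bp inside either end of a gene. Other peaks were put in a gene body where their midpoint lay in a gene, and otherwise took the nearest gene within 100 kb, so a gene named for a peak between genes is its neighbour. This replaced the planned promoter class. 27 gene lists fixed before the data were examined were tested with camera (preset correlation 0.01, with an estimated correlation beside it) and fry over all tested peaks of their genes. Region classes were tested with camera. For this the class between genes also took in peaks over 100 kb from a gene or on unplaced contigs. Motif sets were not tested, since no genome sequence was used here.

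Genes were named by rules fixed before the data were examined. They were the peaks past the threshold that moved one way in both pairs, or, where none passed, the 8 with the smallest p in each direction, 1 per gene, without predicted genes; the highest peak at an end of 18 fixed genes; and up to 4 members of each list with the smallest p. Peaks named outside these rules are said to be so.

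The test was tested on simulated data with the means and spread of the real peaks, in 10 runs with 50 peaks changed per strength and size. With no change simulated, no run gave a call. With changes simulated, a run gave 91 calls on average, of which 8.8 (9.67%) were false, above the 5% the threshold aims at. Intervals of correlations come from leaving out each chromosome in turn. Alternatives covered the scaling (median ratios, totals, loess and a trimmed mean of log ratios), the filter, the pseudocount, library weights, the replicate block, peak width, each library left out, sums per gene and other forms of the list and class tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.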

Results

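Open chromatin was measured by ATAC-seq, in which a transposase cuts and tags accessible DNA, in long-term haematopoietic stem cells (LT-HSCs), the bone marrow cells that can rebuild the blood over a lifetime. The cells came from pooled middle-aged C57BL/6 mice, an inbred laboratory strain, and were sorted and then kept for 18 h in serum-free medium with stem cell factor at 100 ng/ml and thrombopoietin at 50 ng/ml. Insulin-like growth factor 1 (IGF1), a growth hormone-dependent peptide that signals through its own receptor tyrosine kinase, was added at 100 ng/ml in 2 libraries, and vehicle in 2 control libraries. Each library had a value for each of 205376 peaks of median width 428 bp, which covered 116.3 Mb of the mm10 genome. The values were read counts that had been scaled by a factor per library and rounded, and they summed to 49357524 in control 1, 47212491 in control 2, 50058306 in IGF1 1 and 48327144 in IGF1 2. The spacing of the low values showed that 1 read was worth 1.0582 in control 1, 0.912 in control 2, 1.8312 in IGF1 1 and 1 in IGF1 2. The sums therefore stood for about 46600000 reads in peaks in control 1, 51800000 in control 2, 27300000 in IGF1 1 and 48300000 in IGF1 2, so that IGF1 1 was the shallowest library.

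**Figure D1:**
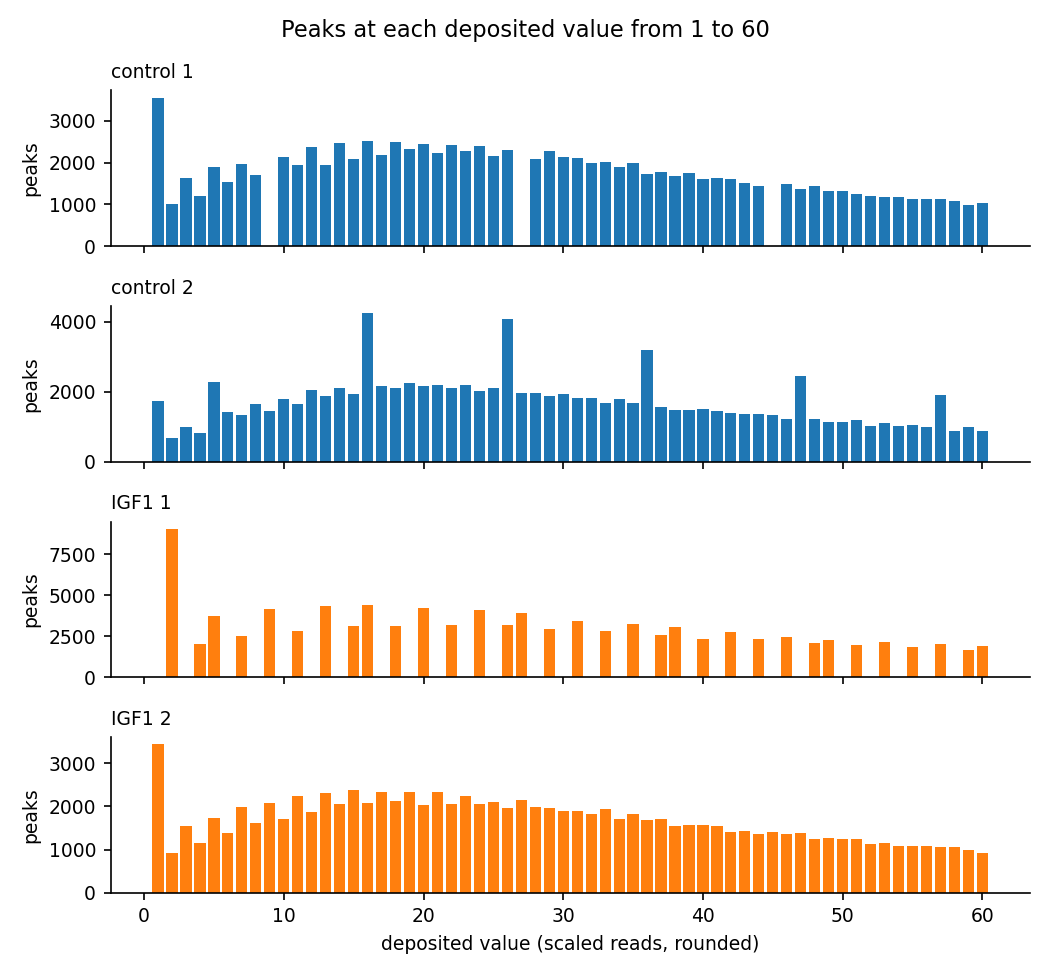
Number of peaks (y axis) at each deposited value from 1 to 60 (x axis, scaled reads rounded to whole numbers), with 1 panel per library and the control libraries in blue and the IGF1 libraries in orange. IGF1 1 leaves the most whole numbers unused and control 1 leaves a few, whereas control 2 has regularly spaced values held by more peaks than their neighbours.

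The first question was whether the libraries separated by treatment. They did not: IGF1 1 stood apart from the other libraries on the first principal component, which held 45.4% of the variance over 197481 peaks, and same-treatment libraries were not the closest. Across peaks, Pearson's r was highest between control 2 and IGF1 2 (0.929) and lowest between IGF1 1 and IGF1 2 (0.892), with 0.925 between the control libraries. The difference of IGF1 from control in pair 1 (IGF1 1 and control 1) had almost no relation to that in pair 2, with r = 0.0010 (95% interval −0.0047 to 0.0067, from leaving out chromosomes in turn) over all tested peaks and −0.0049 over the 47227 peaks with a mean value of at least 200. The difference of number 2 from number 1 was shared between the arms to a larger degree, with r = 0.054 (0.0498 to 0.0582) over all tested peaks and 0.203 (0.194 to 0.212) over the same 47227 peaks. These correlations are across peaks, which are not independent replicates.

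**Figure D2:**
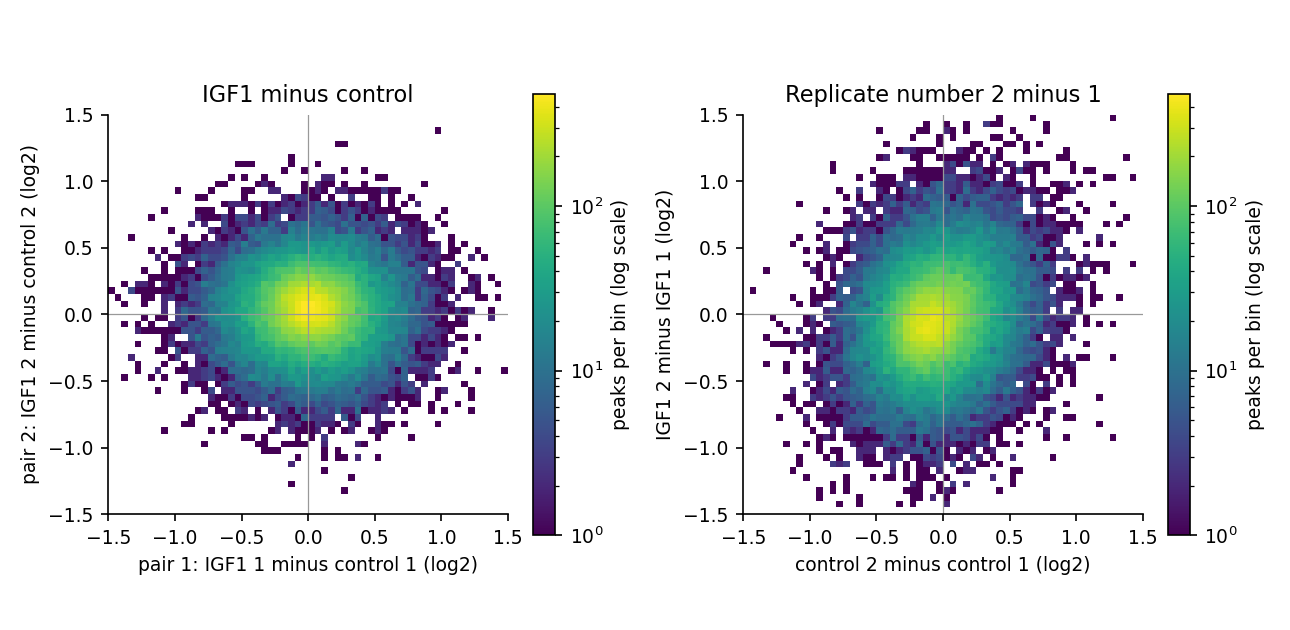
Log2 differences of the 47227 peaks with a mean value of at least 200, in bins of 0.05 coloured by the number of peaks on a log scale. The left panel sets IGF1 minus control in pair 1 (x axis) against pair 2 (y axis), where r was −0.0049, and the right panel sets number 2 minus number 1 in the control libraries (x axis) against the IGF1 libraries (y axis), where r was 0.203; 8 and 17 peaks lie outside the axes.

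The main comparison asked which regions of the genome gained or lost accessibility when middle-aged LT-HSCs were given IGF1. No peak passed the threshold. Among fixed genes of IGF1 signalling, the peak at an end of Igf1r, the IGF1 receptor (chromosome 7, 67950260 to 67954477), had a value of 3795 ± 380 (SD, n = 2) in control and 4030 ± 21.9 in IGF1 libraries, and that of Irs2, an adaptor of the insulin and IGF1 receptors, had 3566 ± 323 and 3685 ± 157. The highest peaks at ends of Foxo1 and Foxo3, transcription factors that insulin signalling keeps out of the nucleus, differed by 0.08 ± 0.11 and 0.15 ± 0.09 on the log2(value + 2) scale (SE). Socs2 and Cish, targets of STAT5, differed by 0.08 ± 0.10 and −0.02 ± 0.09.

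Genes that mark stem cells did not pass the test either. Mecom, a transcription factor needed for stem cell maintenance, differed by 0.03 ± 0.10 on the log2 scale, Meis1 by 0.05 ± 0.10, Procr, a surface receptor used to sort these cells, by 0.13 ± 0.18, and Hlf by 0.16 ± 0.15. Cdkn1c, a cyclin-dependent kinase inhibitor linked to quiescence, had the lowest difference, −0.16 ± 0.16, and Selp, which encodes P-selectin, the highest, 0.39 ± 0.24, from values of 311 and 389 in control and 348 and 596 in IGF1 libraries. Vwf differed by 0.09 ± 0.20. Of the growth factor-inducible genes, Myc differed by 0.16 ± 0.10, Fos by 0.03 ± 0.12, Jun by −0.05 ± 0.09 and Egr1 by 0.13 ± 0.14, beside 0.07 ± 0.11 for Actb. All 18 of these intervals at 95% included 0, the adjusted p was 1 for each in limma, and in 7 of the 18 genes the pairs had opposite signs.

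**Figure D3:**
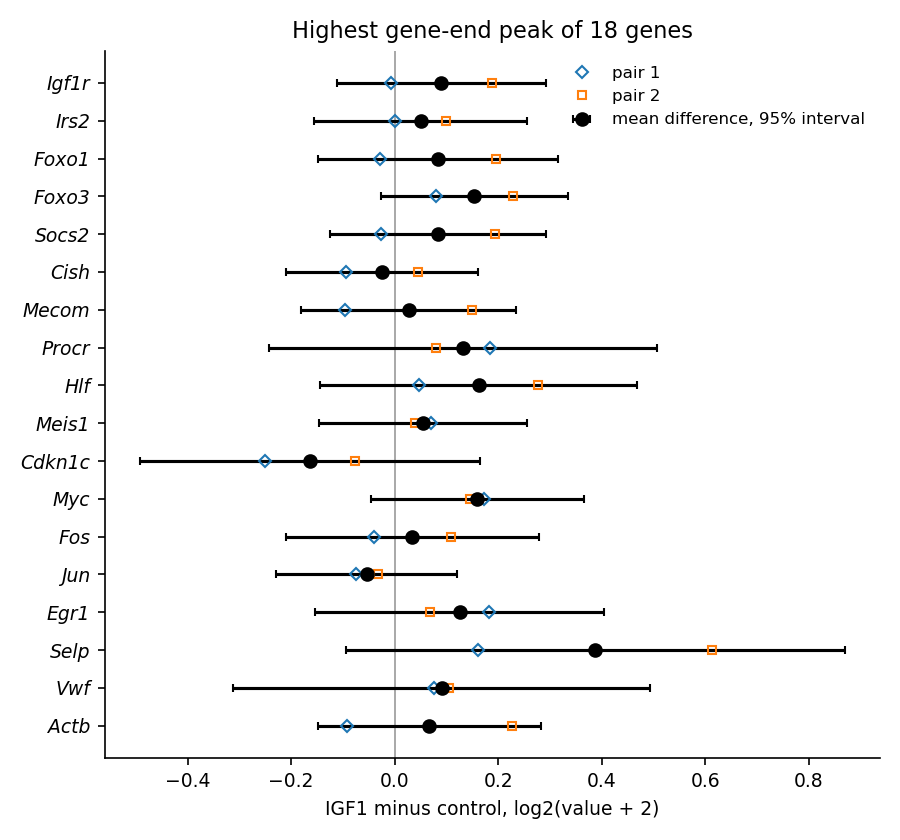
IGF1 minus control on the log2(value + 2) scale (x axis) for the highest peak at an end of each of 18 genes named before the data were examined (y axis). Black points are the mean difference with its 95% interval (n = 2 per group), blue diamonds pair 1 and orange squares pair 2; the means lie between −0.16 for Cdkn1c and 0.39 for Selp, and each interval includes 0.

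The peaks with the smallest p-values that moved one way in both pairs were also not past the threshold. On the higher side in IGF1 libraries they included a peak in the body of Wfdc3 (chromosome 2, 164739707 to 164740638), with values of 328 and 375 in control and 590 and 663 in IGF1 libraries, a log2 difference of 0.83 ± 0.20. A peak at an end of Nle1, a ribosome assembly factor (chromosome 11, 82907554 to 82908690), had 570 and 531 in control and 928 and 794 in IGF1 libraries, a difference of 0.64 ± 0.17. The other 6 were peaks of Tmem161b, Samd4, Sfrp2, Nin, Sdc3 and Tex2, with differences from 1.35 to 2.92. On the lower side, a peak in the body of Myo5c, an unconventional myosin (chromosome 9, 75263931 to 75264667), had 248 and 196 in control and 82 and 72 in IGF1 libraries, a difference of −1.497 ± 0.334. A peak 24445 bp from Sod1, the cytosolic superoxide dismutase, had 108 and 73 against 13 and 12, a difference of −2.65 ± 0.61. The remaining 6 were peaks of Lingo1, Serp2, Syt16, Tbc1d1, Rab27a and Cfap20dc, between −2.85 and −1.31. Each had an adjusted p of 1, and 12 of the 16 peaks lay in gene bodies.

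Of 197481 peaks tested with limma, 0 passed an adjusted p of 0.05 (n = 2 per group). At an unadjusted p under 0.05 there were 6846 peaks, 3360 higher and 3486 lower, against 9874 that chance alone would give, and the median log2 difference was 0.0047. Of the 47227 peaks with a mean value of at least 200, 98.0% differed by less than 0.5 on the log2 scale and 1 by more than 1. With the replicate number as a block, 1 peak passed and 9627 had an unadjusted p under 0.05. That peak, named after its values were seen, was the highest of the table, over a copy of the ribosomal DNA repeat on chromosome 17 (39842794 to 39849077), and was lower in IGF1 libraries by a log2 difference of −0.07 (adjusted p = 0.000859). Its values were 227745 in control 1 and 207696 in IGF1 1, a difference of −0.13, but 198441 in control 2 and 197698 in IGF1 2, a difference of −0.0054. Most of the difference thus came from pair 1. Without control 1, in the fit without the block, where control 2 is set against both IGF1 libraries, it was 0.03 (adjusted p = 1). In simulated libraries of the same spread, 99.4% of 4-fold and 46.6% of 2-fold changes were recovered at peaks with a mean value of at least 200, and 18.2% and 0.2% at weaker peaks. With n = 2 per group, 2-fold changes of weak peaks were thus almost never recovered. The simulation gave all libraries a like spread, without a difference by replicate number or correlation between peaks. Depth was not varied in it.

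Gene groups were compared next, to see whether the peaks of a pathway or cell type moved together. Camera called 0 of 27 lists (smallest adjusted p = 0.976), and 0 had an unadjusted p under 0.05. In the growth factor groups, 463 of 880 peaks of IGF1 and insulin receptor signalling were on the higher side, with a median log2 difference of 0.02. Members with the smallest p were Grb2, an adaptor of receptor tyrosine kinases, at 0.40 ± 0.13, and peaks in or near Insr (−2.15 ± 0.74), Igf1 (−1.54 ± 0.55) and Sos1 (−0.65 ± 0.24). The mTORC1 pathway had the lowest median of the lists, −0.04, with 171 of 401 peaks higher. It included a peak in the body of Rptor at 1.03 ± 0.41 and one in that of Eif4e at −2.57 ± 0.95. The latter had values of 29 and 57 in control and 2 and 11 in IGF1 libraries. FOXO targets had a median of 0.01, with a peak 10960 bp from Trib3 at 2.65 ± 0.86 (3 and 11 in control, 46 and 51 in IGF1 libraries). Members named here and for the lists below are single peaks picked for a small p. Many lay away from gene ends and had low values. Where members of only 1 side are named, other members picked from that list could lie on the other side. Regulators of MAPK feedback had a median of 0.02, with Spred2, an inhibitor of the pathway, at 0.73 ± 0.20, from values of 377 and 341 in control and 663 and 534 in IGF1 libraries. Immediate early genes had a median of 0.03, with Nr4a3 at 0.35 ± 0.13 and Ier5 at −0.47 ± 0.16. STAT5 targets had a median of −0.03, with Stat5a at 1.962 ± 0.708 and Jak2 at 0.90 ± 0.35. A peak near Socs2 was lower, at −0.91 ± 0.37.

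Stem cell and metabolic groups gave similar values. The 1365 peaks of stem cell identity genes had a median log2 difference of 0.01, with 709 higher, and among them Tek at 1.56 ± 0.54 and Prdm16 at −1.54 ± 0.51. Genes that mark aged stem cells had a median of 0.01 over 646 peaks, with Wwtr1 at 0.80 ± 0.28 and Cavin2 at −1.59 ± 0.56. Mitochondrial genes had 158 of 290 peaks higher and a median of 0.03, with Sirt3, a mitochondrial deacetylase, at 0.65 ± 0.24. Sterol and fatty acid synthesis had a median of 0.01, with Acly, which makes cytosolic acetyl-CoA, at −2.24 ± 0.63. Cell cycle genes had a median of 0.02, with a peak 81799 bp from Ccnd1 at 1.71 ± 0.58. Peaks in or near Rb1 (−2.31 ± 0.80), Mki67 (−2.73 ± 1.05) and Cdkn1a (−0.95 ± 0.37) were lower. The medians were 0.01 for MYC and ribosome biogenesis, −0.02 for autophagy and lysosome and −0.01 for p53 and apoptosis. They were 0.03 for interferon response, 0.02 for NF-κB and inflammation, −0.01 for epigenetic regulators, 0.04 for integrin, polarity and cytoskeleton, and −0.01 for housekeeping genes.

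Programs of blood lineages and markers of other cells that a sort could hold gave no call either. The median log2 difference was 0.01 for the lymphoid program, with Ikzf1 at 1.82 ± 0.55, and 0.01 for the myeloid program, with Itgam at −1.27 ± 0.39 and Irf8 at 1.31 ± 0.41. It was −0.0023 for the megakaryocyte and platelet program, with Mef2c at 1.69 ± 0.53, and 0.04 for the erythroid program. The medians were 0.02 for mast cell, basophil and eosinophil genes, −0.03 for T and NK cell markers, 0.01 for B cell markers and 0.01 for stromal and endothelial markers. No member named here passed the test.

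**Figure D4:**
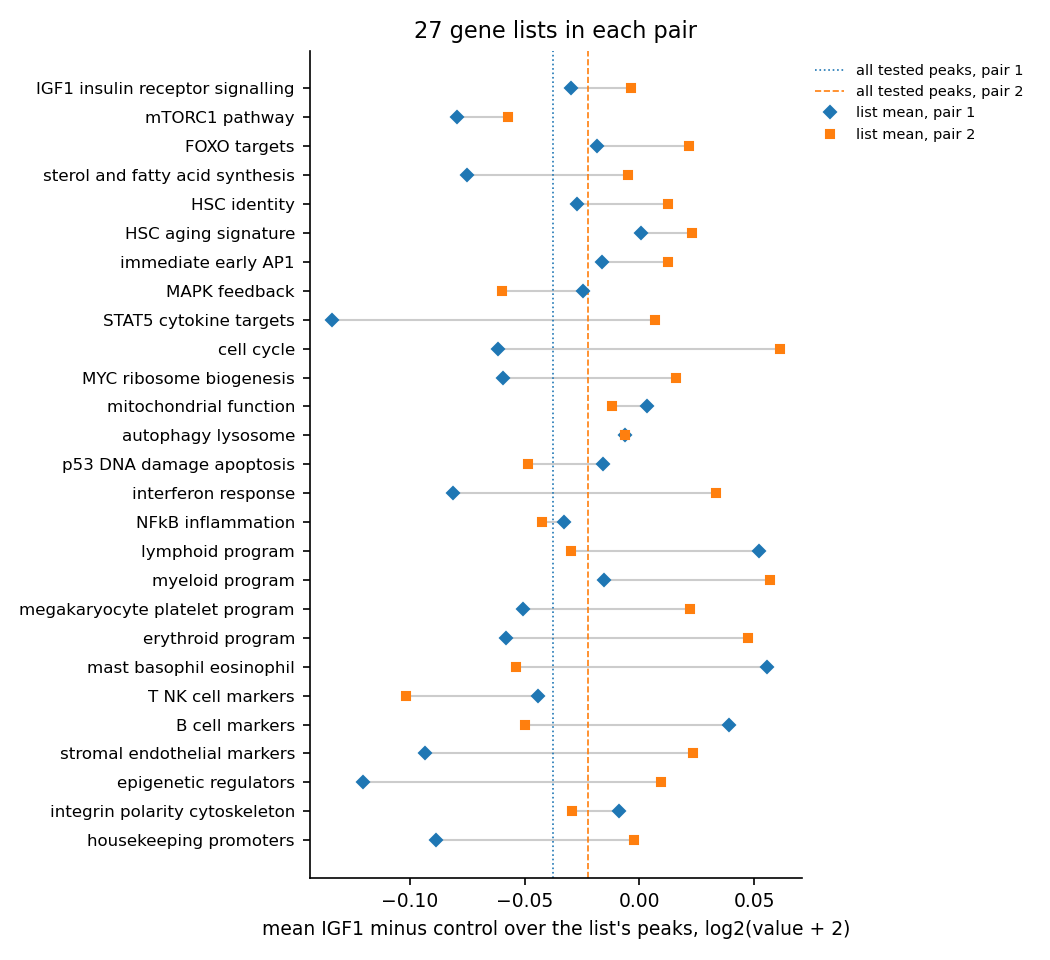
Mean IGF1 minus control on the log2(value + 2) scale (x axis) over the peaks of each of 27 gene lists (y axis), in pair 1 (blue diamonds) and pair 2 (orange squares), with vertical lines at the mean of all tested peaks in pair 1 (dotted) and pair 2 (dashed). In 16 of the 27 lists the means of the pairs lie on opposite sides of 0.

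Over all 27 lists, 0 peaks passed over all peaks tested and 0 adjusted over the list alone (smallest adjusted p = 0.307). With an estimated correlation camera called 0 lists (smallest adjusted p = 0.961), and fry called 0 for one direction (0.940) and 0 for either direction (0.913), with 0 lists at an unadjusted p under 0.05 in either tool. The sign of camera's test differed from that of the median relative to all peaks in 7 lists, which were sterol and fatty acid synthesis, MAPK feedback, autophagy, megakaryocyte, T and NK cell, B cell and stromal genes. In libraries simulated without correlation between peaks, camera called a list shifted by 0.2 on the log2 scale in 10 of 10 runs for each of 3 lists tried, and one shifted by 0.1 in at most 3 of 10.

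The last comparison asked whether IGF1 acted on one kind of region. Peaks at gene ends, which hold the promoters, were 9.78% of tested peaks and held 39.4% of the values. Their share was 40.1% in control 1, 38.7% in control 2, 39.9% in IGF1 1 and 39.0% in IGF1 2, so the control libraries lay farther apart than the groups. The median log2 difference was 0.02 at the 19305 gene-end peaks, 0.0013 at the 103688 peaks in gene bodies and −0.0051 at the 74488 peaks between genes. The last class includes peaks over 100 kb from a gene or on unplaced contigs. None of the 3 classes passed (camera adjusted p = 0.457, 0.865 and 0.865). Without control 1, gene ends passed in the higher direction (adjusted p = 0.000819), and without control 2 or IGF1 1 they lay on the lower side without passing, as they did after loess normalization and width correction. With an estimated correlation the peaks between genes passed in the lower direction (adjusted p = 0.0492). As no peak was called, the share of gene ends among gained and lost peaks was not tested.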

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

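The alternatives with other pseudocounts, library weights, the trimmed mean of log ratios, a minimum mean value of 200, sums per gene and the removal of the 5 highest peaks were chosen after seeing the data. The count of peaks past the threshold stayed at 0 under 19 of 23 alternatives, including each library left out, each scaling and each filter. It was 1 with the replicate block, 1 with width correction and 1 with both, in each case the ribosomal DNA peak on chromosome 17, at a log2 difference of −0.07 with the block and −0.11 with width correction. Most of the first came from pair 1, as pair 2 differed by −0.0054. With width correction both pairs were lower, by −0.15 in pair 1 and −0.07 in pair 2. Without control 1 and without the block the difference was 0.03 on the values as deposited and −0.07 with width correction. Without control 2, IGF1 1 or IGF1 2 it was −0.17, −0.10 and −0.03 as deposited, and −0.15, −0.11 and −0.11 with width correction. Each of these fits leaves a lone library in a group. Without the 5 highest peaks, which include the ribosomal DNA peak, the block gave 0, which is no test of that call. With the block and a minimum mean value of 200, where the peak was kept, 0 peaks passed (smallest adjusted p = 0.210 in limma). In the block's main fit the spread came from the trend over peaks alone. The disagreement of the pairs at the ribosomal DNA peak therefore did not enter its p. Sums per gene with the block gave 1 call, Sgms1, a sphingomyelin synthase gene, higher by 0.14 ± 0.03 (adjusted p = 0.0398). The block changed no other call. The cause of these calls was not tested.

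For the region classes, 0 to 1 passed when 1 library was left out, with the call at gene ends without control replicate 1, where a lone control library is assumed to vary like the others; 1 passed with an estimated correlation (peaks between genes). The cause was not tested. No list passed under any of its alternatives. Of 351 list values under alternatives 42 took the other sign, as did 22 of 378 values of the 18 fixed genes, 15 of them with a library left out; none passed. All 306 values of the peaks chosen by p kept their sign. These peaks had been chosen for a small p and a like sign in both pairs, so this does not show stability.

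The correlation of number differences between the arms was 0.049 at a pseudocount of 0.5 and 0.203 at a mean value of at least 200. That of IGF1 differences between the pairs was −0.022 over the 2000 peaks of highest variance and −0.0049 at a mean value of at least 200. The largest shift of the median log2 difference by a scaling was 0.0264. Weak peaks were measured least well: the median SE was 0.20 on the log2 scale at a mean value of at least 200 and 0.58 below. Count models (DESeq2, the exact test and the quasi-likelihood test), motif sets and GC correction were not run, as the values are not counts and no genome sequence was used; peak width took the place of GC content.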

Other observations

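All tests in this part were chosen after the result was seen. The libraries differed more by replicate number than by treatment. Comparing number 2 with number 1 over both arms, limma called 91 peaks at an adjusted p under 0.05 (2 against 2 libraries), 71 lower and 20 higher in number 2, where the treatment split called 0 and the remaining split of the 4 libraries 0. If the number marks a shared pool of mice, each side of this comparison is a single pool. Its p-values then measure the spread between libraries of a pool, with treatment left in it, and not that between pools. The peaks named here had small p-values and were picked after their values were seen. The call with the smallest p lay at an end of Egr1, an immediate early transcription factor (chromosome 18, 34864830 to 34866643), with values of 1416 and 1846 in the number 1 libraries and 391 and 414 in the number 2 libraries, a log2 difference of −2.001 ± 0.145. The stronger called peak of Egr1 (34859081 to 34864741) differed by less, −0.63 ± 0.05, with 9066 and 10282 against 6108 and 6406. A peak at an end of H3f3b, a histone H3.3 gene, had 2126 and 2152 against 610 and 933. A stronger H3f3b peak differed by less, −0.45 ± 0.06, and a weaker one near the gene by −1.90 ± 0.37. Of the replication-dependent histone genes, 19 of 124 tested peaks were called, in 19 genes, and all 19 were lower in number 2; after loess 9 and after width correction 13 histone peaks were called. H3c14 (−0.91 ± 0.11) and H1f1 (−0.79 ± 0.09) are examples. The histone peaks had a median log2 difference of −0.28, with 106 of 124 lower, beside −0.09 for all gene-end peaks, which left −0.20 relative to gene ends. Immediate early genes had a median of −0.07 over peaks of all classes, below the −0.01 of all tested peaks, above that of gene ends with the values as deposited and below it after loess (−0.05 beside −0.02), and Egr1, with 2 peaks, was the 1 gene of that list called. Under 5 other scalings the histone median lay between −0.29 and −0.20 and that of the immediate early genes between −0.07 and −0.01. The histone list was made after histone genes were seen among these calls, so its count and median describe the calls and are no test of them. The immediate early list, fixed before, did not pass among the 27 lists (camera adjusted p = 0.289). Adjusted over that list and the histone genes alone, a choice made after the calls were seen, it passed (0.0107, and 0.0297 with an estimated correlation, 0.0296 to 0.0474 under the other scalings).

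Of the 20 peaks higher in number 2, the one with the smallest p lay on chromosome 2 (98666015 to 98667497), over 100 kb from any gene. It had 10084 and 9652 against 13954 and 14221 (0.51 ± 0.04). Another such peak on chromosome 2 (98662109 to 98663094) was at 0.34 ± 0.06, and peaks in Sfi1 were at 0.68 ± 0.12 and 0.23 ± 0.05. These peaks on chromosome 2 and in Sfi1 may hold reads from satellite repeats, which was not tested. The treatment of such reads is not given, so these peaks are not taken as changes of a locus or of Sfi1. The higher peaks also included one near Hbb-bs, an adult beta-globin gene (229 and 229 against 556 and 633, 1.37 ± 0.20). Others lay near Lmo2, a regulator of early blood cells (0.62 ± 0.10), near Xbp1, a transcription factor of the unfolded protein response (0.84 ± 0.15), and in Jarid2 (0.58 ± 0.10). The peaks of Hbb-bs, Lmo2, Xbp1 and Jarid2, and the Egr1 peaks, passed under all 6 scalings tried. Other erythroid genes did not pass: Hbb-bt, the other adult beta-globin gene, was at 0.35 ± 0.13 (732 and 873 against 1047 and 996), Car1 at 1.58 ± 0.83, Gypa at 0.15 ± 0.13 and Klf1 at −0.07 ± 0.09. Hba-a1 (−0.17 ± 0.85), Gata1 (−0.02 ± 0.23) and Epor (−0.10 ± 0.10) were also on the lower side. So were Tfrc (−0.05 ± 0.09) and Car2 (−0.08 ± 0.08). Hba-a2 and Slc4a1 were at 0.03 ± 0.54 and 0.01 ± 0.18. Gene ends made up 47.3% of the called peaks and 9.78% of tested peaks, but they were also stronger (median value 584, against 58 in gene bodies and 59 between genes), and strong peaks are called more readily. The balance of calls depended on the scaling: 71 of 91 were lower with the values as deposited, 61 of 123 after scaling to totals, 35 of 83 after loess and 46 of 93 after width correction, and of the 91 peaks 80, 56 and 65 were called again. The ribosomal DNA peak on chromosome 17 was among the 91, lower in number 2 by a log2 difference of −0.13 (adjusted p = 0.000145).

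Noise of single libraries predicts that a difference between the control libraries keeps its sign between the IGF1 libraries in 50% of peaks. The 50% holds only without a shift that peaks share between the numbers. The check used the deposited values alone, where gene ends had a median of −0.09 (−0.02 after loess). Peaks were chosen among those with a mean value of at least 200. Of the 100 of these that differed most between the control libraries, 82% kept their sign (95% exact binomial interval 73.1% to 89.0%, which treats peaks as independent). Of the 100 chosen in the IGF1 libraries, 68% kept their sign in the control libraries. Both values lie above 50%, which argues against noise alone at the chosen strong peaks only as far as such a shift is small. The interval around 82% does not clear a stricter limit of 75% that had been set first. Without a choice, the sign was shared by 58.1% of the peaks of that strength and by 52.2% of all tested peaks. For IGF1 differences, 51% of peaks chosen in pair 1 kept their sign in pair 2. A difference in read depth stays open: the log2 depths lie 0.82 apart in the IGF1 libraries and 0.15 in the control libraries, and the median over histone and immediate early peaks was 0.66 times as large in the former (interval from a bootstrap over genes 0.26 to 1.11), but the histone genes were picked from calls that needed a like difference in both arms. More cells in S phase among the number 1 libraries may account for the histone genes: the 64 end peaks of other cell cycle genes had a median of −0.13, at the 5.49th percentile of 10000 matched random lists, which leaves this open. A difference between the pools of mice or in their handling was not tested and stays open too.

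The lack of an IGF1 difference shared by both pairs could come from too few reads in IGF1 1. At peaks with a mean value of at least 200 the covariance of the pairs' differences was −0.00034, with an upper 95% limit of 0.000391. At peaks with a mean value of at least 1000 the pairs' differences correlated at −0.048 (−0.062 to −0.034), so that part of them was opposed, and opposed differences can hide shared ones in a covariance. Over the peaks with a mean value of at least 200, the number difference, which uses IGF1 1 as well, had a covariance of 0.0181 (0.0171 to 0.0190). A shared difference of that size, whatever its source, was thus visible over many peaks with the reads of IGF1 1. Read depth stays open as a source of it, since number 1 was the shallower library in both arms. The number difference therefore cannot decide whether the reads sufficed to see a difference made by IGF1. Whether too few reads or opposed differences hid a shared one, or smaller or rarer changes were missed, stays open.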
